A study of Mus musculus with 2 samples.

How the data were processed

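Total RNA sequencing of 2 libraries was analysed, both from the nucleoplasmic RNA of mouse bone marrow-derived macrophages treated as the labels describe. Elsewhere the labels call the same material a nuclear fraction. Per the labels, the RNA was depleted of ribosomal RNA, the starting amount was 1 µg for replicate 1 and 500 ng for replicate 2, and the size range was 250 to 400. The labels place both libraries in 1 group, so no comparison between conditions, p-value or adjusted p-value was computed. Nothing in the labels separates the replicates by animal.

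The authors' deposited tables hold 2 quantifications of each library, 1 library per table, on the mm10 assembly with the GENCODE M21 annotation. In the first, per the file headers, each gene and transcript has an expected count, in which reads shared between features are split by a model, and column names are those that RSEM writes. The deposited TPM values are scaled over all features, spike-in and tRNA entries included. The deposited FPKM values are proportional to TPM within a library, per the file headers. Each transcript also has a deposited percent, its share of the TPM of its gene. The deposited tables also give bounds of a credibility interval of TPM, per the file headers, which were not used for any comparison. In the second quantification, whose column names are those that kallisto writes, the authors' tables give an estimated count and TPM per transcript, and these were summed per gene. The aligner, the software versions and whether the counting used strand are not given in the sources used here. Values of overlapping and antisense genes, of gene families and of pseudogenes can therefore contain reads of their partners.

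All 55536 genes of the annotation had a row in the first quantification, and 86 had none in the second. Rows that name no gene were kept out of library sizes and ratios. These were phiX174 (0.766% of expected counts in replicate 1 and 0.272% in replicate 2), 96 ERCC spike-in sequences (0 counts in both) and numbered tRNA entries (16 and 22 counts). Gene counts summed to 29400104 and 17789543 after rounding in the first quantification and to 39148298 and 31973373 in the second. A count of 0, taken as at most 3 counts, allows 0.102 CPM (counts scaled to library size) in replicate 1 and 0.169 in replicate 2. These floors and the counting intervals cover counting error only, since no molecular identifiers are described.

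Expected counts were rounded to whole numbers before scaling. TMM factors from edgeR were 0.944 and 1.06. The log2 ratio of replicate 2 over replicate 1 was computed from TMM-scaled counts with a prior count of 0.5 scaled to library size, over genes with a mean rounded count of at least 10. A log2 ratio beyond 1 was counted as a difference. The common and trended biological coefficient of variation came from edgeR with an intercept-only design. Whether the libraries differed beyond sampling noise was checked with a chi-square over genes. Bootstrap intervals of medians used 2000 draws of genes and describe these libraries. Counting intervals of a ratio are exact binomial 95% intervals (Clopper-Pearson). List and class levels are medians of log2(TPM + 1), with a pseudocount of 1, and are printed as TPM. The retained-intron share is the percent of a gene's transcript TPM on isoforms of that biotype, over genes with at least 1 such isoform, at least 1 protein-coding isoform and at least 1 TPM in both libraries.

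Lists of genes (24 lists, 584 symbols), the tests behind the reported results, their alternatives and the rule for named genes were fixed before the data were examined. The symbols Norad, Cyrano, Oip5os1, Rnu4atac and Rnu6atac matched no gene. A list's median was placed among 10000 seeded random lists of the same size, drawn from nuclear-encoded protein-coding genes and the list's members, or from all genes for the non-coding, small RNA, mitochondrial and sex-linked lists. For retained-intron shares and replicate ratios the random lists were matched on deciles of mean expression. Named were 29 genes whatever their value, the 15 protein-coding genes and 10 long non-coding RNAs of highest mean TPM, the 4 highest and 2 lowest members of each list, the 6 largest ratios in each direction among genes of at least 10 CPM, and the 8 list members with the highest retained-intron share among genes of at least 5 TPM and 100 counts. Several choices were made after the data had been explored. They include the tests that weigh explanations for differences between the replicates, of which those of cytoplasmic mRNA, of a weaker response and of both mitochondrial explanations were chosen after the results they measure were seen. A list was called apart from random lists when its percentile was at most 2.5 or at least 97.5. Ratios were given only for lists of at least 5 tested members. Of the 5 listed symbols with 2 gene IDs, the ID with the higher mean count was used. A named gene was followed across alternatives by the percentile of its level among protein-coding genes. Because the replicate agreement has no spread of its own, any change visible at 2 decimals counted as moved. Rescaling TPM over protein-coding genes and long non-coding RNAs, for the number of protein-coding genes detected and for the comparison of quantifications, was added after the data were seen.

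The alternatives were other TPM and count minimums, the second quantification, expected counts or FPKM in place of TPM, a pseudocount of 0.1, DESeq2 size factors or library totals in place of TMM, a wider class of non-coding isoforms, matching on isoform number and each replicate alone. The calculations were tested on simulated data for 14900 genes, of which 200 were changed. A coefficient of variation of 0.2 was returned as 0.22. Median log2 ratios of -1.94, -1.49, 1.43 and 1.90 were returned for true values of -2, -1.5, 1.5 and 2, and 95.8%, 87.2%, 80.0% and 96.0% of these genes passed a log2 ratio of 1. Of unchanged genes, 4.44% passed it. The simulated coefficient lies below the 0.296 found in these libraries, so this share is a lower background than theirs. A list of 40 genes moved by 0.5 lay at the 99.99 percentile, and 5 of 100 random lists fell outside the central 95%. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.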

Results

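Ribosomal RNA-depleted total RNA was sequenced from the nucleoplasmic fraction of mouse bone marrow-derived macrophages, primary phagocytes grown from bone marrow cells of C57BL/6J mice. The cells had been exposed to 100 ng/ml lipid A, the part of lipopolysaccharide that activates the receptor TLR4, for 12 h. After a washout of 12 h the same dose was given again, and RNA was taken 90 min later. Exposure followed by a repeat stimulus is the layout in which endotoxin tolerance is commonly studied, although the labels state no purpose. The libraries form 1 group of 2 replicates. The labels call them biological replicates but give the same donor entry for both, so their spread may be technical. Replicate 1 was made from 1 µg of RNA and held 29400104 gene counts, and replicate 2 was made from 500 ng and held 17789543. No untreated, singly stimulated, cytoplasmic or whole-cell library was analysed here. The values below are therefore levels within this condition and not induction, tolerance or nuclear enrichment. They are mean ± SD of TPM (n = 2) by the first quantification unless another unit or quantification is named, and ranks are by that measure.

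Protein-coding genes held most of the expected counts assigned to genes, and small RNAs as a class held most of the TPM. Protein-coding genes took 64.6% ± 3.78 of the expected counts and long non-coding RNAs took 14.5% ± 0.812. Malat1, a nuclear speckle RNA, alone held 11.2% ± 0.483 of the counts (n = 2). On the TPM scale, which divides by effective length, small RNAs took 66.4% ± 9.36 and protein-coding genes 17.5% ± 0.456. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, reached 32.4% ± 1.20 of all TPM. Rpph1, the RNA of RNase P, took 8.07% ± 0.552. By the second quantification these were 12.6% ± 0.428 and 2.89% ± 0.155. The order of Rn7sk and Malat1 depends on the unit. In the first quantification Rn7sk took 5.81% ± 0.791 of the expected counts, and Malat1 took 1.88% ± 0.771 of TPM. Small RNAs as a class took 9.22% ± 2.17 of the expected counts. Small RNAs took 73.0% of TPM in replicate 1 and 59.8% in replicate 2, and mitochondrial-encoded RNAs 3.31% of TPM in replicate 1 and 12.6% in replicate 2. In the second quantification, 3 short microRNA entries (Gm24245, Gm24270 and Gm23935) held 37.3% ± 12.0 of TPM but 1.81% ± 1.30 of the estimated counts, whereas all 3 were listed at 0 by the first. A TPM of at least 1 in both libraries was reached by 10340 genes, of which 8499 were protein-coding, 698 were long non-coding and 458 were pseudogenes. At a minimum of 5 TPM the number was 5275. Because small RNAs hold most of the TPM, the threshold is strict for mRNAs. With TPM rescaled over protein-coding genes and long non-coding RNAs, 10595 protein-coding genes reached 1 TPM in both libraries, and 12719 by the second quantification. This rescaling was chosen after the data were seen.

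**Figure D1:**
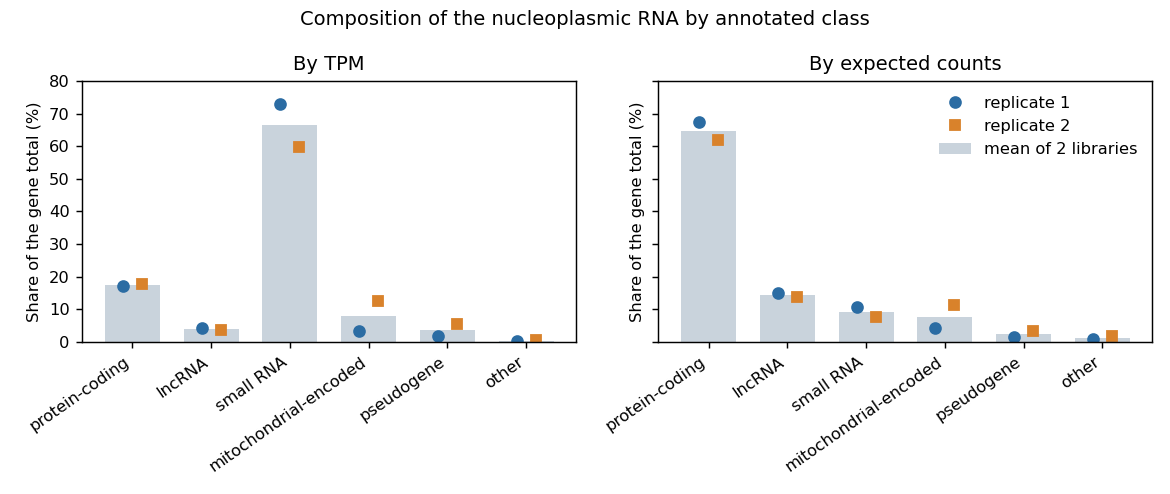
Percent of TPM and percent of expected counts assigned to each RNA class, with a point for each replicate and a bar for the mean. Protein-coding genes lead by counts (64.6% on average) and small RNAs by TPM (66.4% on average).

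The 15 most abundant nuclear-encoded protein-coding genes ranged from 723 to 2543 TPM. Psap, the precursor of the saposins (ENSMUSG00000004207.14, chromosome 10, 60277627 to 60302597, mm10), stood first at 2543 ± 29.1 TPM. The class I antigen-presenting gene H2-K1 followed at 2378 ± 43.7 and the inhibitory receptor gene Lilrb4a at 1624 ± 96.3. The cathepsin genes Ctsb and Ctsd reached 1239 ± 328 and 1191 ± 247, and Fth1, the ferritin heavy chain gene, 1207 ± 274. H2-K1 and H2-D1, and Lilrb4a and Lilr4b, belong to families of similar sequence, so the split of reads within each pair is uncertain. Among long non-coding RNAs, Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) led at 18746 ± 7714. A long non-coding entry of Rmrp, which overlaps the ribozyme entry of that name, followed at 12030 ± 12756. In replicate 1 it stood above Malat1, at 21050 against 13291 TPM. Gm26917 at 956 ± 318 and Gm42418 at 662 ± 260 also lay above Neat1. Both lie at the rRNA gene CT010467.1 on chromosome 17, so the class may hold ribosomal reads. Neat1, the scaffold RNA of paraspeckles, reached 633 ± 209, and Mir155hg, the host transcript of the microRNA miR-155, reached 324 ± 52.7. Gm28872 ranked among the top 10 long non-coding RNAs by TPM on only 34 and 14 counts.

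Genes of the lipid A response were present at high levels 90 min after the second stimulus. Of the 42 immediate-early and primary NF-κB genes, 40 reached 1 TPM in both libraries, and the list median was 52.7 TPM. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) was highest at 559 ± 72.5, followed by the chemokine genes Ccl3 at 404 ± 10.2 and Ccl4 at 401 ± 189. Il1b was at 105 ± 7.50 and Cxcl1 at 28.9 ± 0.502. The early transcription factor genes lay lower, with Egr1 at 12.8 ± 1.52, Fos at 3.93 ± 0.658 and Fosb at 0.245 ± 0.276. Secondary cytokine and effector genes had a lower median, 7.69 TPM, and 16 of 25 reached 1 TPM in both libraries. Their median was 10.9 TPM in replicate 1 and 4.30 TPM in replicate 2. Cd40 stood at 155 ± 33.1, Il12b at 20.6 ± 3.61, Il6 at 13.8 ± 4.43 and Nos2, the inducible nitric oxide synthase, at 8.21 ± 4.30. Cxcl5 and Il33 had 0 counts in both libraries by the first quantification, which allows up to 0.102 CPM in replicate 1 and 0.169 in replicate 2. By the second, Cxcl5 was listed at 0.638 ± 0.595 TPM and Il33 at 0.

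Interferon-stimulated genes had a median of 111 TPM, and 40 of 41 reached 1 TPM in both libraries. Ccl5 was at 1144 ± 174, the antiviral gene Rsad2 at 747 ± 414, Oasl2 at 544 ± 14.5 and Cxcl10 at 397 ± 174. Cxcl9 was lowest at 0.395 ± 0.205. The interferon gene Ifnb1 (ENSMUSG00000048806.4, chromosome 4, 88522025 to 88522774) gave 27.5 TPM from 709 counts in replicate 1 and 5.02 TPM from 69 counts in replicate 2, so its mean of 16.2 ± 15.9 rests on replicate 1. Negative regulators of TLR4 and NF-κB signalling had a median of 24.3 TPM, with Tnip3 at 299 ± 28.6, Tnfaip3 (A20) at 222 ± 22.8 and Nfkbia (IκBα) at 218 ± 82.3. Irak3, an inhibitory kinase-like gene, was at 24.5 ± 3.48 and Il10 at 4.02 ± 0.0283. Il1rl1 had 0 counts in both libraries by the first quantification and was listed at 0.207 ± 0.134 TPM by the second. All 30 TLR4 pathway components reached 1 TPM in both libraries, with a median of 16.5 TPM and a range of 2.27 for Tab1 to 349 for Ikbke. Median levels of these 5 lists lay at or above the 99.99 percentile of 10000 random lists of protein-coding genes, a description of these libraries and not a test. This rank does not set them apart. Macrophage identity, antimicrobial, metabolic, stress-response, ribosomal protein and housekeeping genes all lay at the 100 percentile.

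**Figure D2:**
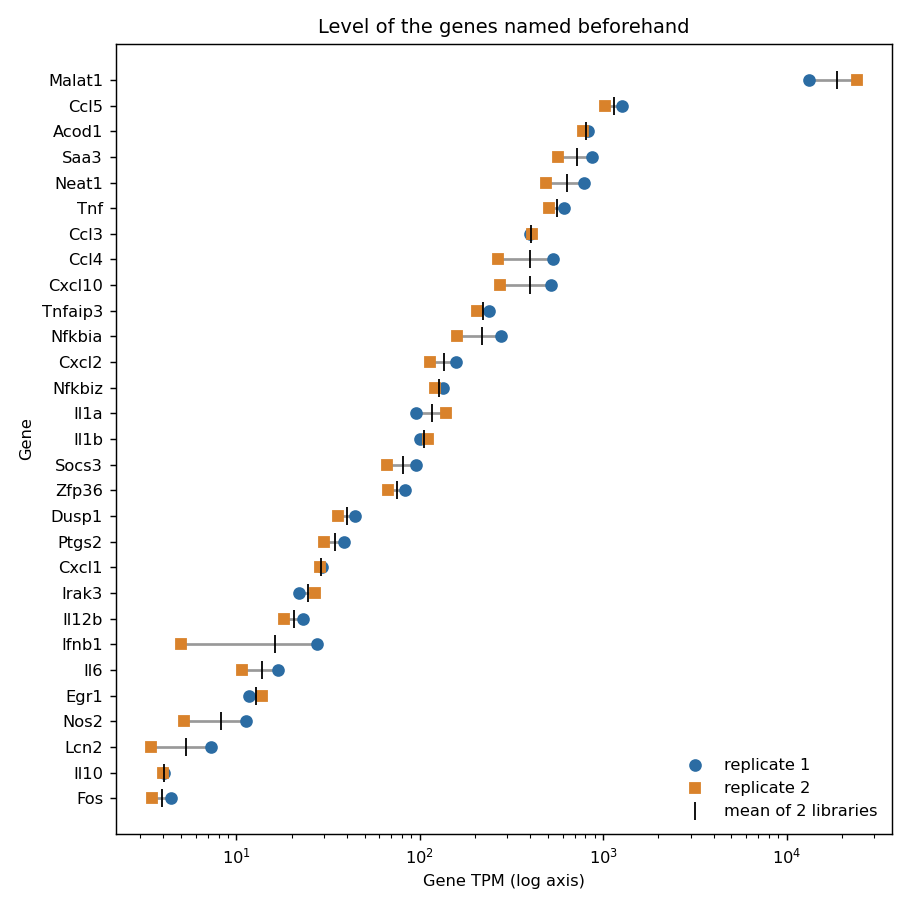
TPM of the genes named in advance, on a log axis, with a point for each replicate, a tick for the mean and a grey line between the replicates. Levels run from Malat1 at 18746 TPM to Fos at 3.93 TPM, and the replicates of Ifnb1 lie far apart at 27.5 and 5.02 TPM.

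Macrophage identity genes had a median of 141 TPM, and 29 of 30 reached 1 TPM in both libraries. Gpnmb was at 1211 ± 225, and Cx3cr1 was lowest at 0.140 ± 0.0849. Antimicrobial, acute-phase and scavenger genes had a median of 61.5 TPM. Lyz2 stood at 899 ± 283, Acod1, which makes itaconate, at 801 ± 41.0, and Saa3 at 718 ± 217. Lcn2 was at 5.35 ± 2.72, and Camp and Ptx3 were both at 0.055. Metabolic and hypoxia genes had a median of 16.2 TPM and stress-response genes 25.3 TPM, led after Acod1 by Hk3 at 147 ± 89.7 and by Sqstm1 at 231 ± 6.88. Alternative activation genes had a median of 0.568 TPM, at the 67.0 percentile, and of 0.50 TPM in replicate 1 and 1.00 TPM in replicate 2, with Tgm2 at 31.5 ± 8.37, Mrc1 at 30.7 ± 12.3 and Arg1 at 0.615 ± 0.544. Arg1 is outside the rule for named genes and was chosen after its value was seen. Cell cycle genes had a median of 0.845 TPM at the 80.3 percentile, with Mki67 at 21.4 ± 5.96 and Plk1 at 0.065 ± 0.0636. Among genes with a mean count of at least 10, cell cycle genes instead lay low, at the 0.12 percentile.

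Markers of other cell types were low. The medians were 0.0694 TPM for 14 neutrophil and granulocyte genes (0.04 and 0.075 TPM in replicates 1 and 2), 0.277 for 12 dendritic cell genes, 0.0736 for 13 erythroid and megakaryocyte genes (0.03 and 0.12 TPM in replicates 1 and 2) and 0.06 for 13 stromal and endothelial genes. They were 0.00995 for 12 B cell genes (0.02 and 0 TPM in replicates 1 and 2) and 0 for the T and NK cell and the mast cell and basophil lists. The exceptions above 2 TPM by the first quantification were Csf3r at 54.0 ± 5.31, Cd4 at 12.2 ± 4.84, Vwf at 11.2 ± 1.56, Kdr at 7.77 ± 3.93 and Hdc at 2.15 ± 1.18. By the second, Cd3d at 2.91 ± 2.37, Pecam1 at 4.26 ± 4.16, Fscn1 at 2.88 ± 0.849 and Alas2 at 2.19 ± 1.82 also exceeded 2 TPM, and Hdc was at 1.23 ± 0.336. Xist was at 155 ± 33.3, and Ddx3y, Uty, Kdm5d and Eif2s3y, which lie on the Y chromosome, were listed at 0 in both libraries. By the second quantification Uty and Kdm5d were listed at 2.61 ± 2.14 and 1.73 ± 1.46 TPM.

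**Figure D3:**
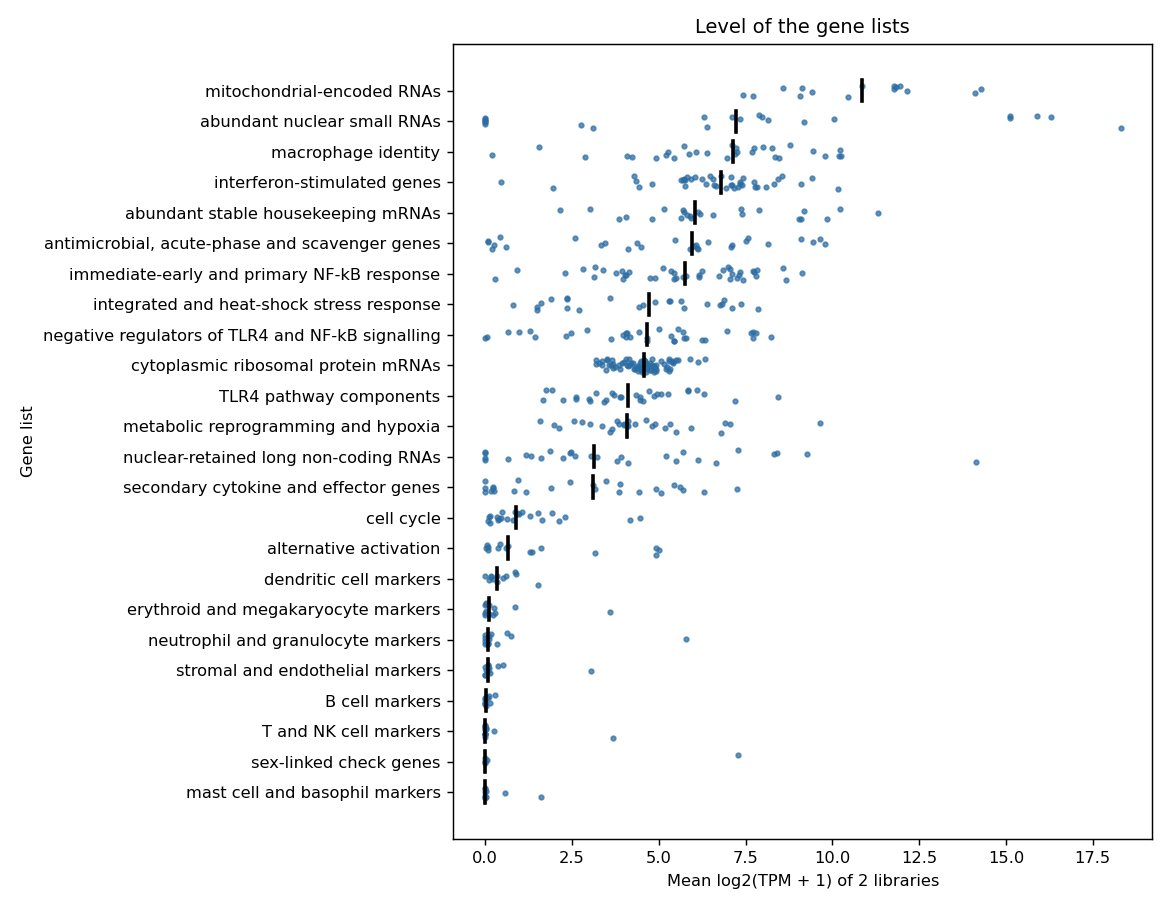
Mean log2(TPM + 1) of both libraries by the first quantification for each member of each gene list (points), with the list median as a black line. The medians are 1853 TPM for mitochondrial-encoded RNAs, 148 TPM for the list of nuclear small RNAs and 141 TPM for macrophage identity genes, and those of markers of other cell types lie near 0.

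RNAs typical of the nucleus and of the cytoplasm were both present. Nuclear-retained long non-coding RNAs had a median of 7.80 TPM over 28 genes, although Malat1 and Neat1 lay far above it. That list also holds Gas5 and Snhg genes, whose spliced RNAs are not confined to the nucleus. Rian and Mirg had 0 counts in both libraries by the first quantification, and were listed at 4.96 ± 3.83 and 0.211 ± 0.194 TPM by the second. Abundant nuclear small RNAs had a median of 148 TPM over 22 genes, with 275 TPM in replicate 1 and 97.0 TPM in replicate 2. This list also holds Rn7s1, Rn7s2, Rny1 and Rny3, which are not confined to the nucleus, so it is not a purely nuclear set. Rn7s1 and Rn7s2 are near-identical copies and share their reads, so their values are uncertain. Ribosomal protein mRNAs had a median of 23.0 TPM, from Rpl14 at 8.10 ± 0.156 to Rps24 at 80.5 ± 18.9. Housekeeping mRNAs had a median of 64.5 TPM, with Actb at 922 ± 18.6, and mitochondrial-encoded RNAs a median of 1853 TPM. The mitochondrial median was 1213 TPM in replicate 1 and 3942 TPM in replicate 2. By mean TPM mt-Atp8 and mt-Co1 led, and mt-Atp8 was at 7574 TPM in replicate 1 and 52266 TPM in replicate 2. The median of the nuclear-retained RNAs, as log2(TPM + 1), differed from that of ribosomal protein mRNAs by -1.38 ± 0.12, from housekeeping mRNAs by -2.86 ± 0.03 and from mitochondrial RNAs by -7.93 ± 1.11 (n = 2). By log2(CPM + 1) the differences were -0.63, -3.24 and -6.53, so their size depends on the measure. These differences compare different genes within a library, and with a list that is not purely nuclear they are no level of nuclear RNA.

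Isoforms annotated as retaining an intron held a median of 28.8% of a gene's TPM in replicate 1 and 32.6% in replicate 2, a mean of 30.7% ± 2.68 over 5524 genes. In 1125 of these genes, 20.4%, the share was above 50%. Lower shares than in random lists of like expression were found for housekeeping mRNAs, with a median of 16.4% at the 1.54 percentile, for macrophage identity genes, with 16.1% at the 1.73 percentile, and for alternative activation genes, with 4.13% at the 0.04 percentile over only 6 genes. Primary NF-κB genes at 31.2% and interferon-stimulated genes at 34.4% lay within the central 95% of random lists, as did the other 7 lists that had 5 or more eligible genes. Matching the random lists on isoform number instead put macrophage identity genes at the 5.35 percentile, replicate 2 alone put them at the 2.79 percentile, and housekeeping mRNAs lay at the 3.98 percentile in replicate 1 alone and at 3.71 by the second quantification, all within the central 95%. Ribosomal protein mRNAs, with a median of 24.8% at the 2.67 percentile, lay at the 0.11 percentile in replicate 2 alone and at 2.08 in replicate 1 alone. In replicate 2 alone metabolic genes lay at the 1.47 percentile and stress-response genes at 1.39. The highest shares among list members were those of Rps16 at 94.9% ± 2.98, Rpl5 at 89.0% ± 1.29, Pfkp at 88.3% ± 6.50, Tnip3 at 83.4% ± 0.156 and Cd83 at 81.5% ± 1.76 (n = 2). By the second quantification the share of Pfkp was 64.3%, and that of Ptprc was 45.0% against 74.9% ± 7.48 by the first. Reads from unspliced RNA can be assigned only to annotated isoforms, so these shares are not a measure of splicing.

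Interferon-stimulated genes, mitochondrial RNAs and the listed small RNAs were among the groups that differed between the replicates. All 41 interferon-stimulated genes were lower in replicate 2, with a median log2 ratio of replicate 2 over replicate 1 of -0.93, and 17 were below -1. Cmpk2 at -2.01, which is outside the rule for named genes and was chosen after its value was seen, Rsad2 at -1.55 and Cxcl10 at -1.23 were among them, and Oasl2 was at -0.25. Secondary cytokine genes had a median of -0.66 (17 of 19 lower), primary NF-κB genes -0.50 (38 of 42 lower) and negative regulators -0.47 (22 of 32 lower). The NF-κB and negative regulator lists share members, such as Nfkbia, Tnfaip3 and Dusp1, so their shifts are not independent. Ifnb1 was at -2.80, with an exact 95% counting interval of -3.18 to -2.45. TLR4 pathway components had a median of 0.00, with 15 higher and 15 lower. The other lists within the central 95% of random lists all had negative medians, from -0.41 for alternative activation to -0.22 for macrophage identity genes. The latter lay at the 58.35 percentile of lists of like expression, so by TMM-scaled counts abundant genes tended to be lower in replicate 2. The sign can depend on the unit. In TPM, medians rose from replicate 1 to replicate 2 for macrophage identity genes (125 to 151) and negative regulators (23.0 to 25.7). Those of interferon-stimulated genes (129 to 88.1) and primary NF-κB genes (58.9 to 50.7) fell in TPM too. The list of abundant nuclear small RNAs, which also holds Rn7s1, had a median of -1.64 and was lower in 16 of 16. Ribosomal protein mRNAs were at -0.31, lower in 64 of 75, and the median of all 11355 protein-coding genes tested was -0.05. Mitochondrial-encoded RNAs had a median of 1.16. Of these, 12 of 15 were higher, such as mt-Atp8 at 2.23 and mt-Nd1 at 1.83, and mt-Co2 at -0.57 and the ribosomal RNAs mt-Rnr1 at -1.26 and mt-Rnr2 at -2.15 were lower. Of these, mt-Rnr1 is outside the rule and was added after its value was seen. Loci of the TEC class, single-exon transcripts whose status the annotation leaves open, had a median of 0.65 over 1101 loci.

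Of 14831 genes with a mean count of at least 10, 1984 differed more than 2-fold between the replicates, 1116 of them higher and 868 lower in replicate 2. Among the 11355 protein-coding genes tested the balance turned, with 417 higher and 570 lower, whereas TEC loci had 319 higher and 32 lower. Higher genes made up 56.2% of all differing genes with TMM scaling and 72.5% with library totals, which move the median log2 ratio of all genes from 0.01 to 0.18. Without a filter on counts they made up 43.2% of 7212. Stromal and endothelial markers had a median of -1.0 over 6 genes, at the 0.32 percentile of random lists, but lay at the 97.2 percentile by the second quantification. The other 7 lists outside the central 95% were the 4 response lists, ribosomal protein mRNAs and small RNAs, all at or below the 0.11 percentile, and mitochondrial-encoded RNAs at the 100 percentile. The extremes that follow are from genes of at least 10 CPM. Gm28439, part of a nuclear copy of mitochondrial sequence on chromosome 1 (24611535 to 24612410), had 0 counts in replicate 1 and 50781 in replicate 2. B430305J03Rik had 2553 counts in replicate 1 and 0 in replicate 2. These values are of the first quantification. By the second, Gm28439 was at 235 TPM in replicate 1 and 2191 TPM in replicate 2, a log2 ratio of 2.24, and B430305J03Rik was listed at 0 in both.

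**Figure D4:**
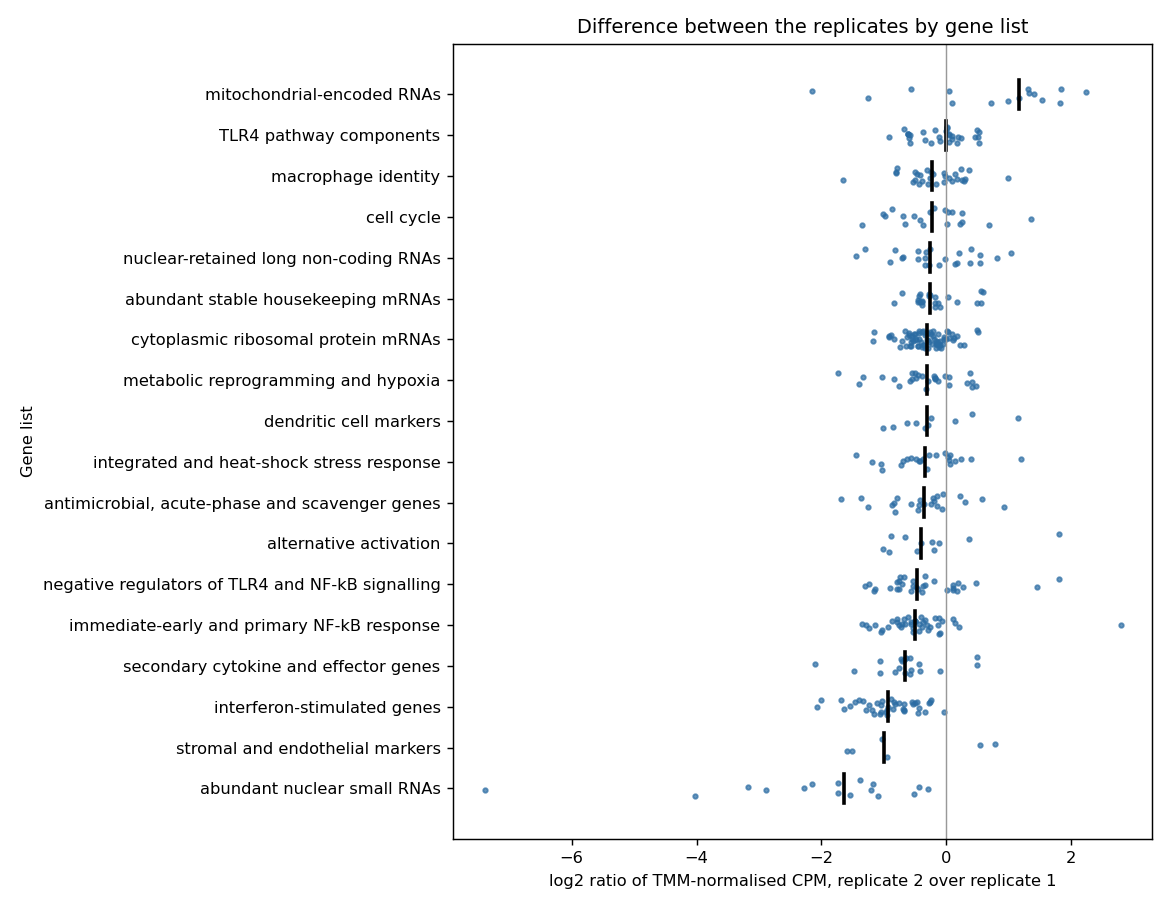
Log2 ratio of replicate 2 over replicate 1 (TMM-scaled CPM) for each tested member of each gene list (points), with the list median as a black line. Interferon-stimulated genes (-0.93) and the list of nuclear small RNAs (-1.64) lie on the lower side and mitochondrial-encoded RNAs (1.16) on the higher side.

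Across 12138 genes, log2(TPM + 1) of the replicates correlated with Pearson's r of 0.932 and Spearman's rho of 0.914. Genes are not independent replicates, so no p-value is given. The common biological coefficient of variation was 0.296. The chi-square of the counts per degree of freedom was 150, so the tables do not hold 1 library deposited again. It does not show whether the replicates came from separate animals or cultures. Since each side of these ratios is 1 library, they compare the libraries and have no replicate check.

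The first and second quantifications of the same reads differed for many genes. Of 13185 genes at 1 TPM or more in both libraries by either, 1222 were so only by the first and 2845 only by the second, and 4211 differed more than 2-fold in mean TPM. In replicate 2 alone these numbers were 732, 5384 and 6320, and in replicate 1 alone 6670 genes differed more than 2-fold. Tnf was at 559 ± 72.5 TPM by the first and 262 ± 10.5 by the second, and Psap at 2543 ± 29.1 and 1166 ± 286. The median log2 ratio of the second over the first, over genes detected by both, was -0.53. When TPM was rescaled over protein-coding genes and long non-coding RNAs, an alternative chosen after seeing the data, that median was 0.02, with 180 genes detected only by the first and 4565 only by the second.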

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

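The tests of cytoplasmic mRNA, of a weaker response and of both explanations for mitochondrial mRNAs were chosen only after the results were seen. With 1 group, the design names no biological difference between the replicates, so none was compared between groups.

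The sequencing control phage phiX174, which no comparison uses, had 227052 expected counts in replicate 1 and 48578 in replicate 2. Both values were singled out because they lie above the limit of 3 counts that a count of 0 allows.

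Interferon-stimulated genes were lower in replicate 2, by a median log2 ratio of -0.88 relative to protein-coding genes. That background takes in genes of all levels. Macrophage identity genes, also abundant, moved by a median of -0.22, so the fall against genes of like level may be smaller. Transcript length bias is argued against, since the list lay at the 0 percentile of 10000 random lists of matched length. More cytoplasmic mRNA in replicate 1 would have lowered ribosomal protein and housekeeping mRNAs as much, if both groups have a like cytoplasmic share. These moved by -0.25 (95% bootstrap interval -0.33 to -0.16), less but in the same direction. No library here measured the cytoplasmic share, so a partial contribution is not excluded. An equally weaker response of all lipid A targets would have moved primary NF-κB genes as much. The difference from these genes was -0.43, with 0.01% of 10000 reassignments of members below it. Reassignment treats genes as replicates, and each side is 1 library. It therefore describes an unequal fall of the 2 lists in these libraries and not its cause. A graded weaker response, in which NF-κB targets fell less, stays open. So do a partial contribution of cytoplasmic mRNA, the different RNA amounts and any difference between the cultures.

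Mitochondrial mRNAs were higher in replicate 2, by 1.36 relative to protein-coding genes. More cytosolic RNA in replicate 2 would have raised ribosomal protein and housekeeping mRNAs too, and these moved by -0.25. Reads shifting between the mitochondrial genes and the nuclear copy on chromosome 1 would have cancelled in their sum, which still moved by 1.29. Mitochondria carried over with the nuclei may account for the rise, and this was not tested. Neither was the depletion of ribosomal RNA, which could bear on the fall of mt-Rnr1 and mt-Rnr2.

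TEC loci were higher in replicate 2, by a median of 0.65. Long non-coding RNAs (0.21) and pseudogenes (0.28) were higher by less, and protein-coding genes (-0.05) and small RNAs (-1.05) were lower. Transcript length bias is argued against, since TEC loci lay at the 100 percentile of 10000 length-matched random lists. Those lists were not matched on expression, so a trend with expression level was not tested. Genomic DNA is argued against too, since reads over 1468 silent receptor genes reached 7.72% of the gain (upper bound 7.96%). More unspliced pre-mRNA in replicate 2 is a candidate explanation, as loci in introns of the same strand rose by 0.34 more than loci that overlap no other gene (95% bootstrap interval 0.18 to 0.60). Loci that overlap no other gene still moved by 0.38 (95% bootstrap interval 0.16 to 0.53), which pre-mRNA of annotated introns leaves open, and those in introns of the opposite strand by 0.65, over 87 loci, where strand use in the counting is not known.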

How the results depend on the processing

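For the number of protein-coding genes detected and the comparison of quantifications, rescaling over protein-coding genes and long non-coding RNAs was chosen after seeing the data; the other alternatives were fixed before. Of 372 values of main results under an alternative, 317 kept their direction and their side of the threshold or moved by less than their spread. For composition, retained-intron share and nuclear against cytoplasmic levels, a single replicate always lies within the SD of 2 replicates. Those single-replicate values could not count as moved, so the 317 overstates how much was checked. Median shifts of interferon-stimulated genes ran from -0.77 with library totals to -1.08 with the second quantification, and those of mitochondrial RNAs from 1.14 to 1.33. Among named genes the level percentile moved beyond the replicate spread for 125 of 187 with the second quantification, 50 without replicate 1, 21 without replicate 2 and 4 with FPKM. The cause of the changes that follow was not tested, except where a stricter or looser minimum alters which genes are counted. Under a setting, lists with fewer than 3 members gave no level, and lists with fewer than 5 gave no replicate shift or retained-intron share.

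At 5 TPM, 5275 genes and 4734 protein-coding genes were detected. By expected counts, protein-coding genes took 64.6%, long non-coding RNAs 14.5%, small RNAs 9.22% and other classes 1.35%. By the second quantification protein-coding genes took 12.0% of TPM, long non-coding RNAs 2.93%, pseudogenes 17.8% and other classes 0.734%. With a mean count of at least 10, cell cycle genes turned from the upper to the lower side, at the 0.12 percentile, and dendritic cell markers (0.01) and stromal markers (0) became low, since the filter removes silent genes from the random lists. The retained-intron share was 36.0% by the second quantification and 36.4% over all isoforms without a coding or NMD biotype. Its percentile for macrophage identity genes was 5.35 with matching on isoform number and 0.03 to 2.79 with each replicate alone. Single replicates gave 1.47 to 2.67 for metabolic genes, 1.39 to 41.1 for stress-response genes, 0.11 to 2.08 for ribosomal protein mRNAs and 0.61 to 3.98 for housekeeping mRNAs. Ribosomal protein mRNAs lay at 2.04 at a gene TPM of 5, and housekeeping mRNAs at 3.71 by the second quantification.

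The common coefficient of variation was 0.261, r 0.961 and rho 0.948 at a mean count of 100; 0.306, 0.963 and 0.922 with no filter; and 0.345, 0.915 and 0.889 by the second quantification. Genes differing between replicates numbered 624 at a mean count of 100, 7212 with no filter and 4016 by the second quantification. By the second quantification the replicate shift of alternative activation genes (0.57), stress-response genes (0.23) and cell cycle genes (0.21) fell below the central 95% of random lists, and stromal markers turned from the lower to the upper side, at the 97.2 percentile. Between quantifications, 31 genes were detected by the first alone, 1280 by the second alone and 2396 differed more than 2-fold among genes of at least 5 TPM in either. Each replicate alone gave 732 to 1384, 2841 to 5384 and 6320 to 6670, and rescaled TPM gave 180 and 4565 for the genes detected by the first or the second alone and 5860 that differed. The nuclear-retained RNAs differed from ribosomal protein mRNAs by -0.99 by the second quantification and -0.63 by log2(CPM + 1), and from housekeeping mRNAs by -2.26 and -3.24 and, with a pseudocount of 0.1, by -2.99. From mitochondrial RNAs they differed by -6.53 by log2(CPM + 1). Depth limits the low genes most, with a floor of 0.102 CPM in replicate 1 and 0.169 in replicate 2.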

Other observations

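Shares on retained-intron isoforms differed widely among abundant genes, while primary NF-κB and interferon-stimulated genes as lists lay within random lists. Lilrb4a had 97.3% ± 0.0552 of its TPM on such isoforms and its relative Lilr4b 67.9% ± 1.61 (n = 2). Clec4e, a receptor for mycobacterial glycolipid, had 66.4% ± 5.69, Oasl2 64.0% ± 3.33, the phosphatase gene Dusp1 60.7% ± 4.71, the kinase gene Ikbke 59.4% ± 9.27 and H2-K1 58.7% ± 12.8. Ccl5 had 43.3% ± 2.24 and Tnfaip3 39.0% ± 10.3. Other abundant genes had little, with Ctsd at 0.697% ± 0.211 and H2-D1 at 3.48% ± 0.569. These genes come from the named genes, and this set was chosen after its values were seen.

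Other gene groups held a few abundant members. Ikbke was the highest of the TLR4 pathway components at 349 ± 68.3 TPM, with Cd14 at 147 ± 24.0 and Irak2 at 78.4 ± 0.707. The cholesterol exporter gene Abca1 was at 112 ± 17.6 and the glucose transporter gene Slc2a6 at 126 ± 58.8, whereas Ch25h was at 2.08 ± 1.02. Among stress genes Hspa8 was at 165 ± 9.30, Hspa5 at 140 ± 38.3, Nfe2l2 at 118 ± 28.1 and Chac1 at 0.745 ± 0.0495. Pcna was at 17.0 ± 0.516 and Ccnd1 at 3.93 ± 0.00707.

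Pseudogenes took 1.86% of TPM in replicate 1 and 5.64% in replicate 2 by the first quantification, and 14.6% and 21.1% by the second. In the nuclear copy of mitochondrial sequence on chromosome 1, Gm10222 (24612407 to 24612700) had 5530 and 21765 counts by the first quantification and was listed at 0 TPM by the second.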
